A study of Mus musculus with 2 samples.

How the data were processed

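Single-cell RNA sequencing counts of mouse brain were analysed in 2 pooled samples, 1 per group: sorted brain (3 and 12 months) and total brain (2 and 24 months). Per the labels' protocols, 2 mice were grouped per genotype and age, tissue was digested with enzymes at 37 C, passed through a 70 µm strainer, cleared of debris and red cells, and about 9000 cells were loaded per well of a droplet system. The deposited matrices hold raw UMI counts for 31053 genes, with cells already called by Cell Ranger and barcode suffixes 1 to 4 pooled in each matrix. Cell Ranger is given as 3.0.2 in the submitters' processing notes, and as 3.0.2 (sorted) and 3.1.0 (total) per the file headers, with the mm10 genome. The annotation release, and whether depth was equalised between suffixes, are not given in the sources used here. The matrices held 0 columns of other samples.

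Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, which were 74.6% of sorted and 63.8% of total barcodes. Doublets were called with Scrublet in each suffix and were not removed in the values given. Counts were scaled to 10000 per cell and log transformed. Both samples were clustered together without integration, on 2000 variable genes, 30 principal components and 15 neighbours, with the Leiden method at resolution 1. A cluster took the name of a class when at least 50% of the class's markers, and at least 3, were raised at least 2-fold over the other clusters with 10 CPM added to both levels. It was left unnamed when at least 80% of the markers of another class (other than erythroid) were raised too, when its depth was low and no own marker led it, or when its 10 leading genes held more markers of another class. There were 19 marker lists. Microglia-like cells were clustered again at resolution 0.5.

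Levels are UMIs summed over the cells of a class per 1000000, with exact Poisson intervals, and shares of cells have exact Clopper-Pearson intervals, all at 95%. Classes with at least 100 cells in each sample were compared between samples, which left 3: microglia-like (9072814 sorted and 2904400 total UMIs), choroid plexus epithelial-like (13235061 and 3295179) and oligodendrocyte-like (449916 and 1799490). No test was made between samples. Log2 ratios add 1 CPM to each level. There were 17 gene lists, and the genes were found in the files by symbol except for 1 of the 22 disease-associated microglia genes. Members needed 10 UMIs over both samples. Each list's median was placed among 10000 random lists of the same size drawn within 20 bins of mean level, and its interval comes from 500 Poisson resamples of the counts. A gene with 0 UMIs in 1 sample was given a bound from a floor of 3 counts over the class. With members at 0 set to that bound, the median was −0.70 for proliferation genes in microglia-like cells, −2.89 for complement and −1.60 for cytokine genes in choroid plexus-like cells, and −5.37 for class II and 0.94 for barrier genes in oligodendrocyte-like cells. Shares of cells with a UMI were repeated with each cell thinned to 1000 UMIs.

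Genes were named by rule: at least 50 CPM in 1 or both samples, a ratio of at least 2, and ranges over suffixes with at least 50 cells of the class that do not overlap between samples, ranked by log2 ratio. The top 12 in each direction were named in microglia-like cells and the top 8 in choroid plexus-like cells. Predicted genes were left out, and markers of other classes are given apart as possible free RNA or doublets. The rule gave no gene in oligodendrocyte-like cells, because no suffix of the total sample held 50 of them. Filters, lists, markers and this rule were fixed before the data were examined. Gene positions come from GENCODE M21 (GRCm38), which matched 31011 gene IDs.

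Alternatives were a looser filter (200 genes, 20% mitochondrial) and a stricter filter (1000 genes, 5%), removal of called doublets, equal weight per suffix, leaving out each suffix, Leiden resolutions 0.5 and 2 (0.25 and 1 for subclusters), clustering each sample alone, a pseudocount of 10 CPM, no UMI minimum or 50 UMIs, levels without mitochondrial and ribosomal protein genes, and TMM scaling. The calculation was tested on simulated data, drawn as Poisson counts from the pooled profile of a class at the depth of each sample, with 100 genes changed 2-fold and 100 genes 4-fold in the total sample. The median error was −0.01 on the log2 scale for both folds in microglia-like cells and −0.01 and −0.0010 in choroid plexus-like cells, and 100% of the genes lay within 0.5 of the true value. The changed genes were drawn from those with at least 50 CPM, and no spread between suffixes or libraries was simulated. The test thus checks the arithmetic and does not cover genes at low levels or differences between suffixes. A changed list of 15 genes lay at percentile 100 and an unchanged list at 74.2 in microglia-like cells, and at 100 and 27.0 in choroid plexus-like cells. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 (TMM only).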

Results

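Single-cell RNA sequencing of mouse brain was carried out on 2 pooled samples, 1 in each group. The sorted brain sample pooled cells of male mice aged 3 and 12 months after fluorescence-activated cell sorting, and the gate of the sort is not given in the sources used here. The total brain sample pooled unsorted cells of male and female mice aged 2 and 24 months, although its age label gives 240 months for the older mice. Wild type mice and mice without STING, the adaptor protein that relays the detection of DNA in the cytosol, were pooled in each sample. Each count table also pools 4 barcode suffixes, and no source used here ties a suffix to an age or a genotype. The sorted sample held 13499 barcodes with 36822467 unique molecular identifiers (UMIs), a median of 2019 UMIs and 836 genes per barcode. The total sample held 14674 barcodes with 48226525 UMIs, a median of 1416 UMIs and 858 genes per barcode. After removal of barcodes with few genes or a high mitochondrial share, 10076 cells of the sorted sample and 9367 cells of the total sample remained, with 31220601 and 33498788 UMIs. There are no replicates: sort, ages and sexes differ together between the samples. The Cell Ranger versions of the file headers differ too (3.0.2 and 3.1.0). So do the estimated pools of barcode sequences, at 797 for the sorted and 3362 for the total sample, in the units given below. Far fewer sequences were shared between the samples than within either, which argues against 1 barcode list for both. Library chemistry may thus differ as well, although the labels name the same chemistry for both samples. No difference between the samples therefore has a replicate check or a single named source. Bracketed ranges are 95% intervals that cover counting error only, exact for levels, shares and folds (Poisson, Clopper-Pearson and binomial) and from resampled counts for list medians. Levels are UMIs per 1000000 UMIs of a class (CPM).

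The cell classes of the samples were compared first, since the series title places the work on resident cells. The sorted brain sample was mostly microglia-like, the resident macrophages of brain tissue, and choroid plexus epithelial-like, the cells that secrete cerebrospinal fluid. The total brain sample was mostly neuron-like. Lymphocytes and macrophages of the brain borders made up much of the rest of the sorted sample, while vascular and glial classes made up much of the rest of the total sample. Microglia-like cells were 41.3% [40.3–42.3] of the sorted sample and 5.01% [4.57–5.47] of the total sample. Choroid plexus-like cells were 24.9% [24.1–25.8] and 3.11% [2.76–3.48]. Neuron-like cells were 58.2% [57.2–59.2] of the total sample, and 1 such cell was found among 10076 of the sorted sample, a share of 0.00992%. B cell-like cells were 6.46% of the sorted and 0.235% of the total sample, T cell-like cells 6.03% and 0.299%, and border macrophage-like cells 4.32% and 0.395%. Monocyte-like cells (1.94% and 0.0534%) and neutrophil-like cells (1.25% and 0.0641%) were also a larger part of the sorted sample. Endothelial-like cells, which line the vessels, were 5.95% [5.48–6.44] of the total sample, and 0 of the sorted cells fell in this class, for which the upper limit is 0.0366%. Oligodendrocyte precursor-like cells showed the same pattern, with 1.47% of the total sample and 0 sorted cells. Astrocyte-like cells were 5.05% of the total and 0.228% of the sorted sample, and erythroid-like cells 2.69% and 0.0595%. Oligodendrocyte-like cells, which make myelin, were close in share, at 1.499% [1.27–1.76] of the sorted and 1.27% [1.05–1.52] of the total sample. Fibroblast-like cells were 0.0893% of the sorted and 0.801% of the total sample, neuroblast-like cells 0.308% and 0.181%, and ependymal-like cells 0.189% and 0.171%. The fibroblast shares leave out an unnamed cluster, 14, that raised 71% of the fibroblast markers. It held 3.89% of the sorted and 0.480% of the total cells, so the direction for fibroblasts depends on its naming.

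**Figure D1:**
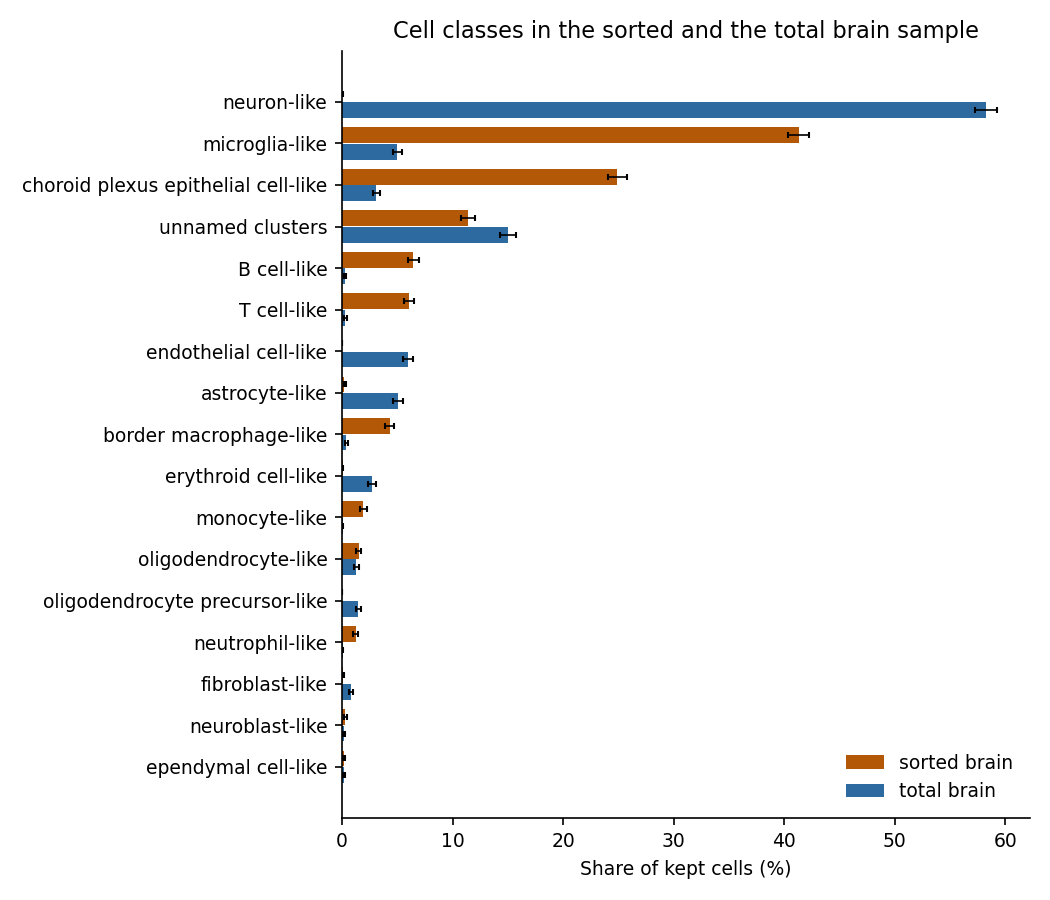
Share of kept cells (percent, horizontal axis) in each class for the sorted and the total brain sample; bars start at 0 and error bars are exact 95% intervals that cover counting error only. Microglia-like cells were 41.3% of the sorted sample and neuron-like cells 58.2% of the total sample.

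Several classes were built of different clusters in the samples, so a cluster filled mostly by 1 library may be that library rather than a type of cell. In the sorted sample, the microglia-like cells lay in cluster 2 (45.8%), cluster 4 (33.5%) and cluster 6 (20.5%), while 79.3% of those in the total sample lay in cluster 16, led by Cebpa. Cluster 6, led by the chemokine and cytokine genes Ccl4, Ccl3 and Tnf, held 11.9% of the microglia-like cells of the total sample, or 56 cells. Choroid plexus-like cells lay mostly in cluster 0 in the sorted sample (92.2%) and in cluster 18 in the total sample (73.9%). Cluster 29, also choroid plexus-like, was led by Dlk1 and the mast cell protease genes Tpsb2, Mcpt4 and Cma1, held 99 sorted cells and 1 total cell, and 59% of its cells were called doublets. The border macrophage-like cluster 12 was led by class II antigen presentation genes together with the basophil protease genes Prss34 and Mcpt8. Its leading genes also held the border macrophage markers Pf4 and Ms4a7 and the dendritic cell marker Cd209a. In it 100% of the border macrophage markers were raised, and 43% of those of monocytes and of dendritic cells, so it may be a mixture. Oligodendrocyte-like cells lay in cluster 24 in the sorted sample (99.3%) and in cluster 28 in the total sample (93.3%). The doublet caller marked 1.23% of the sorted cells and 0.117% of the 9367 total cells, so it found almost no doublets in the latter and cannot be relied on there.

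Neuron-like cells of the total sample fell in 6 clusters whose leading genes differ by brain region and transmitter. The cluster of 2303 cells led by Camk2a and Slc17a7, a glutamate transporter gene, was followed by 1432 cells led by genes that include Sst and Gad1, of inhibitory neurons. A further 956 cells were led by Gabra6, Cbln1 and Neurod1, genes of cerebellar granule neurons. There were 459 cells led by Rgs9 and Adcy5, genes of striatal projection neurons. The remaining clusters held 188 cells with Kit and Pvalb and 117 cells with Ntng1 and Shox2 among their leading genes.

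No class was given to 8 of the 35 clusters, which held 11.4% [10.8–12.1] of the sorted and 15.02% [14.3–15.8] of the total cells. The largest, cluster 7, mixed astrocyte and oligodendrocyte markers in 806 total cells and 2 sorted cells. Cluster 14, led by Mgp, Nov and Igfbp6, held 392 sorted and 45 total cells. In it 71% of the fibroblast markers and 30% of the astrocyte markers were raised. It went unnamed because its leading genes held more astrocyte than fibroblast markers. Cluster 15, led by Spp1, Cst7 and Lpl, genes of lipid-handling microglia, together with haemoglobin genes, held 287 sorted and 122 total cells. Cluster 22, led by the cytotoxic lymphocyte genes Gzma, Gzmb and Xcl1, held 188 sorted and 4 total cells. Cluster 32, led by the mast cell genes Tpsb2, Mcpt4 and Cma1 with Csf2 and Gata3, held 61 sorted cells and 1 total cell. The vascular clusters 17 (haemoglobin and endothelial genes) and 20 (mural and endothelial genes) held 123 sorted and 213 total cells and 30 sorted and 216 total cells, so endothelial markers were also found in the sorted sample, outside the named class. Cluster 31 held 67 sorted cells with B cell and microglial markers, of which 22.4% were called doublets.

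The series title names cytosolic DNA sensing, and the genotype label names STING, so the genes of this pathway were compared between classes within each sample. Tmem173, which encodes STING, was a microglial gene in both samples. Mb21d1, which encodes cGAS, the enzyme that detects DNA and makes the messenger that activates STING, was also highest in microglia-like cells. Ifi204 and Zbp1, other sensors of nucleic acids, were instead highest in monocyte-like cells of the sorted sample. Tmem173 (ENSMUSG00000024349) lies on chromosome 18 from 35733679 to 35740554 in GRCm38, and Mb21d1 (ENSMUSG00000032344) on chromosome 9 from 78430526 to 78443237. Tmem173 was at 159 CPM [151–168] in the microglia-like cells of the sorted sample and 136 CPM [123–150] in those of the total sample, 1.17-fold [1.05–1.31] higher in the sorted sample. With both genotypes pooled, each level is a mean over them, and the part of the gene missing from the knockout is not given in the sources used here, so a UMI of the gene is no check of genotype by itself. Without suffix 1 the level in the sorted sample was 46.7 CPM, without suffix 2 it was 253 CPM, and without suffix 3 the level in the total sample was 58.6 CPM.

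Levels of Tmem173 in microglia-like cells lay far apart between suffixes, while those of Mb21d1 did not. Tmem173 in suffixes 1 to 4 of the sorted sample was at 326, 2.07, 22.2 and 235 CPM. In suffixes 1 to 4 of the total sample, it was at 3.07, 226, 306 and 5.83 CPM. Mb21d1 was at 27.6, 27.1, 23.1 and 30.7 CPM in the suffixes of the sorted sample and at 24.6, 20.6, 37.4 and 32.6 CPM in those of the total sample.

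**Figure D2:**
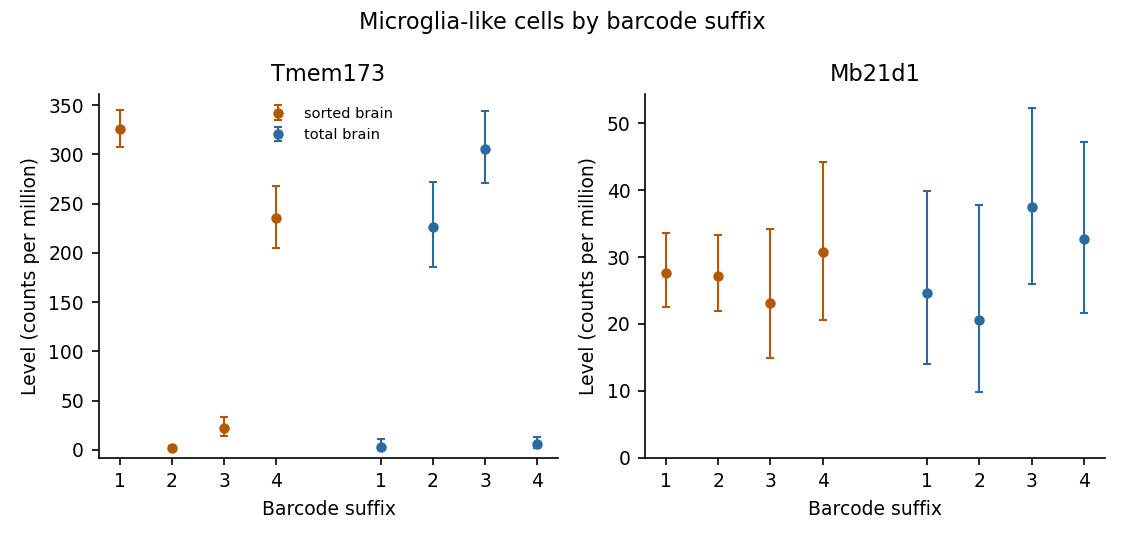
Level of Tmem173 and of Mb21d1 (CPM, vertical axes) in the microglia-like cells of each barcode suffix (horizontal axes) of the sorted and the total brain sample, with exact 95% intervals that cover counting error only. Tmem173 ranged from 2.07 to 326 CPM in the sorted and from 3.07 to 306 CPM in the total sample.

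Among the other classes of the sorted sample, Tmem173 was at 33.6 CPM [24.9–44.3] in border macrophage-like, 27.8 CPM [16.2–44.5] in monocyte-like, 24.9 CPM [16.8–35.5] in B cell-like and 19.7 CPM [13.2–28.3] in T cell-like cells. In choroid plexus-like cells it was at 3.32 CPM [2.42–4.46]. In the total sample, endothelial-like cells had 6.25 CPM [4.38–8.65], astrocyte-like cells 6.26 CPM [2.30–13.6] and neuron-like cells 2.99 CPM [2.06–4.20], while 0 UMIs were seen in 138 oligodendrocyte precursor-like cells. Without suffix 1 of the sorted sample, Tmem173 was at 21.8 CPM in border macrophage-like, 14.6 CPM in monocyte-like, 12.5 CPM in T cell-like and 1.83 CPM in choroid plexus-like cells. Without suffix 3 of the total sample it was at 1.93 CPM in endothelial-like and 3.76 CPM in astrocyte-like cells, and without suffix 4 at 9.75 CPM in the latter. A UMI of Tmem173 was found in 24.2% of microglia-like cells of the sorted sample and 34.1% of those of the total sample, whose median depths were 2081 and 6256 UMIs. With each cell thinned to 1000 UMIs, which left out 180 and 19 cells below that depth, the shares were 13.9% and 12.9%. Choroid plexus-like cells, taken as a class that should lack the gene, had a UMI in 1.43% of sorted cells at a median of 4191.5 UMIs, or 0.322% when thinned, and in 0.344% of total cells at a median of 7198 UMIs.

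Mb21d1 was at 27.2 CPM [23.9–30.8] in microglia-like cells of the sorted sample and 30.3 CPM [24.3–37.3] in those of the total sample, a difference within counting error. It was at 14.1 CPM [8.73–21.6] in border macrophage-like, 6.77 CPM [4.82–9.26] in endothelial-like and 4.99 CPM [3.76–6.50] in neuron-like cells. Ifi204, an interferon-inducible DNA sensor, was at 203 CPM [169–242] in monocyte-like and 107 CPM [90.9–125] in border macrophage-like cells, against 14.5 CPM in microglia-like cells of the same sample. Zbp1, a sensor of Z-form nucleic acid, was at 165 CPM [135–201] in monocyte-like and 78.8 CPM [65.1–94.5] in T cell-like cells, against 3.53 CPM in microglia-like cells. Samhd1, which degrades the building blocks of DNA, was at 581 CPM [522–645] in monocyte-like, 268 CPM in B cell-like and 229.5 CPM in neutrophil-like cells of the sorted sample, and at 148 CPM [138–158] in endothelial-like cells of the total sample. Aim2, the DNA sensor of an inflammasome, was at 49.4 CPM in microglia-like cells of the sorted and 75.7 CPM in those of the total sample. Irf3, the transcription factor downstream of STING, was at 65.6 and 51.3 CPM in microglia-like cells and at 129 CPM [108–154] in astrocyte-like cells. Ddx41 was at 91.0 CPM [85.5–96.8] in neuron-like cells, and Trex1, a DNA exonuclease gene, had 0 UMIs in each class compared. Whether Trex1 is not expressed or its reads were not counted cannot be told from these data.

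**Figure D3:**
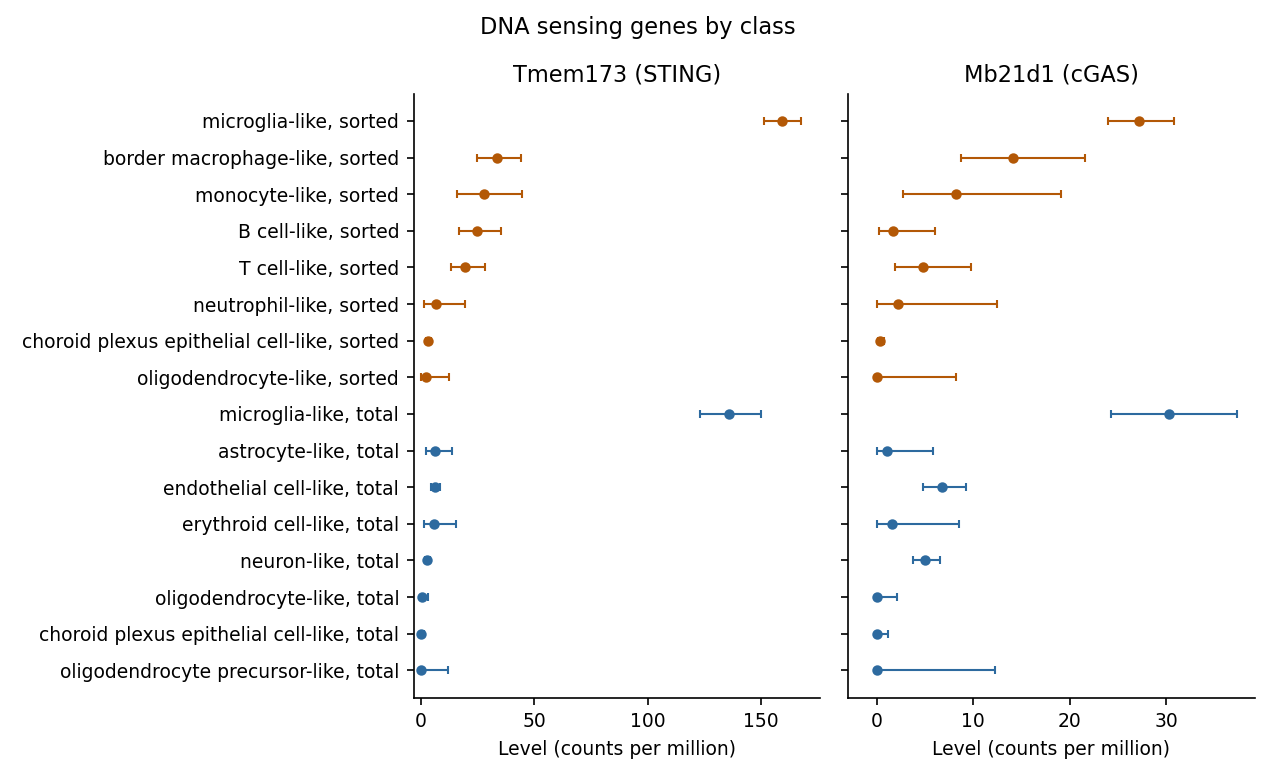
Level of Tmem173 (STING) and Mb21d1 (cGAS) in CPM (horizontal axes) for each class with enough cells in the sorted and the total brain sample, with exact 95% intervals that cover counting error only. Microglia-like cells had the highest Tmem173 level in both samples, at 159 and 136 CPM.

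Other programmes tied to ageing and immunity were also compared between classes within a sample. Interferon response genes were highest in monocyte-like and border macrophage-like cells of the sorted sample and in endothelial-like cells of the total sample. Class II antigen presentation was concentrated in border macrophage-like and B cell-like cells. The former class also had dendritic cell and basophil genes among its leading genes, so its levels may include those cells. Cdkn1a, the cell cycle inhibitor p21 used as a marker of senescence, was highest in endothelial-like cells. The summed level of the type I interferon response list was 8999 CPM in monocyte-like, 4648 CPM in border macrophage-like, 1767 CPM in T cell-like and 719.5 CPM [702–737] in microglia-like cells of the sorted sample. In the total sample it was 3061 CPM in endothelial-like, 1102 CPM [1064–1141] in microglia-like and 201 CPM in neuron-like cells. Ifitm3, which blocks virus entry, made up much of it, with 5963 CPM in monocyte-like, 1636 CPM in border macrophage-like and 1178 CPM in endothelial-like cells. The summed class II list was 67449 CPM in border macrophage-like, 37137 CPM in B cell-like and 7906 CPM in monocyte-like cells, against 885 CPM in sorted microglia-like cells. Cdkn1a was at 877 CPM [853–901] in endothelial-like cells, 67.9 CPM in astrocyte-like and 22.7 CPM [19.96–25.7] in neuron-like cells of the total sample. In the sorted sample it was at 242 CPM in border macrophage-like, 237 CPM in monocyte-like and 79.0 CPM in microglia-like cells. The endothelial-like cells also carried the barrier genes Cldn5 (5302 CPM), Slc2a1 (2974 CPM), Abcb1a (1459 CPM) and Mfsd2a (268 CPM), and the adhesion genes Vwf (278 CPM), Vcam1 (127 CPM, or 77.7 CPM without suffix 3) and Icam1 (118 CPM). Astrocyte-like cells had Gfap, a filament gene of reactive astrocytes, at 176 CPM and the complement gene C4b at 203 CPM.

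Microglia-like cells of the total sample were then compared with those of the sorted sample. They had higher levels of interferon response genes, of genes of disease-associated microglia such as Apoe and Spp1, of mitochondrially encoded genes and of immediate early genes, which tissue dissociation induces. Class II antigen presentation genes were lower. Homeostatic genes as a list were at the middle of random lists, although P2ry12 and Tmem119, receptors and surface proteins of resting microglia, were lower. Without the cytokine-led cluster, with 56 total cells, the disease-associated list was not higher and the interferon list was at the middle of random lists. These total cells numbered 28, 24, 2 and 2 in suffixes 1 to 4, so this setting overlaps with leaving out suffixes 1 and 2. Without suffix 2 of the total sample, the interferon list was not above random lists either. In suffixes 3 and 4 of the total sample, Apoe and Spp1 were below the level of the whole sorted sample. Log2 ratios are of total over sorted from CPM plus 1. Weighted trimmed mean (TMM) scaling lowers the log2 ratios of this class by up to 0.42, less for genes near 0 in a sample, and each list median is set beside the median of 10000 random lists of the same size and mean level, a description of these libraries and not a test. Across 1559 genes, which are not independent replicates, the log2 ratios of microglia-like and choroid plexus-like cells had a Pearson correlation of 0.783 and a Spearman correlation of 0.774.

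The type I interferon response list had a median log2 ratio of 0.83 [0.67–0.93] in microglia-like cells, against 0.22 for random lists, at percentile 98.6, and 21 of 22 members were higher in the total sample (17 with TMM). Its genes included Ifit2, at 3.53 and 18.6 CPM in the sorted and total samples, Ifit3 (12.3 and 33.4 CPM) and Ifitm3 (48.1 and 92.6 CPM). Without suffix 2 of the total sample the median was 0.01, at percentile 11.2, and Ifit2, Ifit3 and Ifitm3 were at 4.96, 9.10 and 41.4 CPM there, the last 2 below the sorted sample. Without the cytokine-led cluster the median was 0.33, at percentile 51.6, and without suffix 2 of the sorted sample it was 0.55. The disease-associated microglia list had a median of 1.97 [1.63–2.15], above all random lists, with 13 of 21 members higher in the total sample (12 with TMM). Apoe, a lipid carrier gene, was at 1139 CPM in the sorted and 5648 CPM in the total sample, 4.96-fold [4.84–5.08], and Spp1, which encodes osteopontin, was at 21.6 and 663 CPM, 30.7-fold [26.5–35.8]. Gpnmb had 0 UMIs in microglia-like cells of the sorted sample and 81.6 CPM in those of the total sample, at least 247-fold higher against a floor of 3 counts over the class. Values of this class leave out the unnamed cluster 15, led by Spp1, Cst7 and Lpl, which held 287 sorted and 122 total cells. Lgals3 (16.1 and 113 CPM) and Lpl (31.9 and 127 CPM) were also higher in the total sample, while Cd68 (1068 and 677 CPM) and the protease genes Ctsd (11475 and 8467 CPM) and Ctsb (2722 and 2019 CPM) were lower. Without the cytokine-led cluster this median was −0.14, and without suffix 1 of the total sample it was 0.54. Without that suffix, Spp1 was at 152 CPM, Lgals3 at 64.3 CPM and Lpl at 31.5 CPM, close to the sorted sample, and without suffix 2 of the total sample Apoe was at 3635 CPM and Gpnmb at 12.8 CPM. Spp1 in the sorted sample was at 33.6 CPM without suffix 1 and 9.47 CPM without suffix 4. In suffixes 3 and 4 of the total sample, Apoe (738 and 543 CPM) and Spp1 (9.91 and 5.83 CPM) were below the level of the whole sorted sample.

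The cytosolic DNA sensing list had a median of 0.36 [0.18–0.54] in microglia-like cells, with 10 of 12 members higher in the total sample (6 with TMM), but the direction flipped to −0.02 with TMM, and the list lay at percentile 75.3 of random lists. Homeostatic genes had a median of −0.17 [−0.20 to −0.15], against −0.18 for random lists, and 8 of the 12 members are among the markers that define the class. Of these, P2ry12 was at 4490 and 2157 CPM in the sorted and total samples and Tmem119 at 2948 and 1341 CPM, while Sall1 (120.5 and 259.6 CPM) was higher in the total sample. Class II genes had a median of −1.43 [−1.68 to −1.22], below all random lists, with Cd74 at 122 and 52.7 CPM and H2-Aa at 31.3 and 4.48 CPM; in the total sample without suffix 1 these were 31.1 and 0.888 CPM. The B cell gene Igkc and the neutrophil gene S100a8 were higher in the sorted sample, which also held more border macrophage-like and B cell-like cells, the classes with the highest class II levels. Class I genes stayed near random lists at −0.08, with the direction of H2-K1 (504 and 701 CPM) opposite to that of B2m (4404 and 1973 CPM). Complement genes had a median of −0.28, with C1qa at 12026 and 9029 CPM. The inflammatory cytokine list had a median of 0.04 (flipped to −0.37 with TMM), with Ccl4 at 2558 and 1528 CPM and Tnf at 142 and 152 CPM (94.3 CPM in the total sample without suffix 2). Immediate early genes had a median of 0.72 [0.68–0.76], against −0.17 for random lists, and Fosb (98.3 and 736 CPM) and Egr1 (359 and 1589 CPM) had some of the larger ratios. The median of the 11 mitochondrially encoded genes was 1.54 [1.497–1.59], and 11 of 11 were higher in the total sample. Proliferation genes had a median of −0.72 [−1.20 to −0.42], with Pcna at 52.2 and 38.2 CPM. The senescence list had a median of 0.96, although Cdkn1a was lower in the total sample (79.0 and 40.3 CPM), and its median was −0.17 without suffix 1 of the total sample. The endothelial adhesion (1.10), blood-brain barrier (0.97) and reactive glia (0.65) lists lay between percentiles 87.6 and 89.4, at low levels in this class, and the sex-linked list had a median of 0.16 (flipped to −0.21 with TMM).

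**Figure D4:**
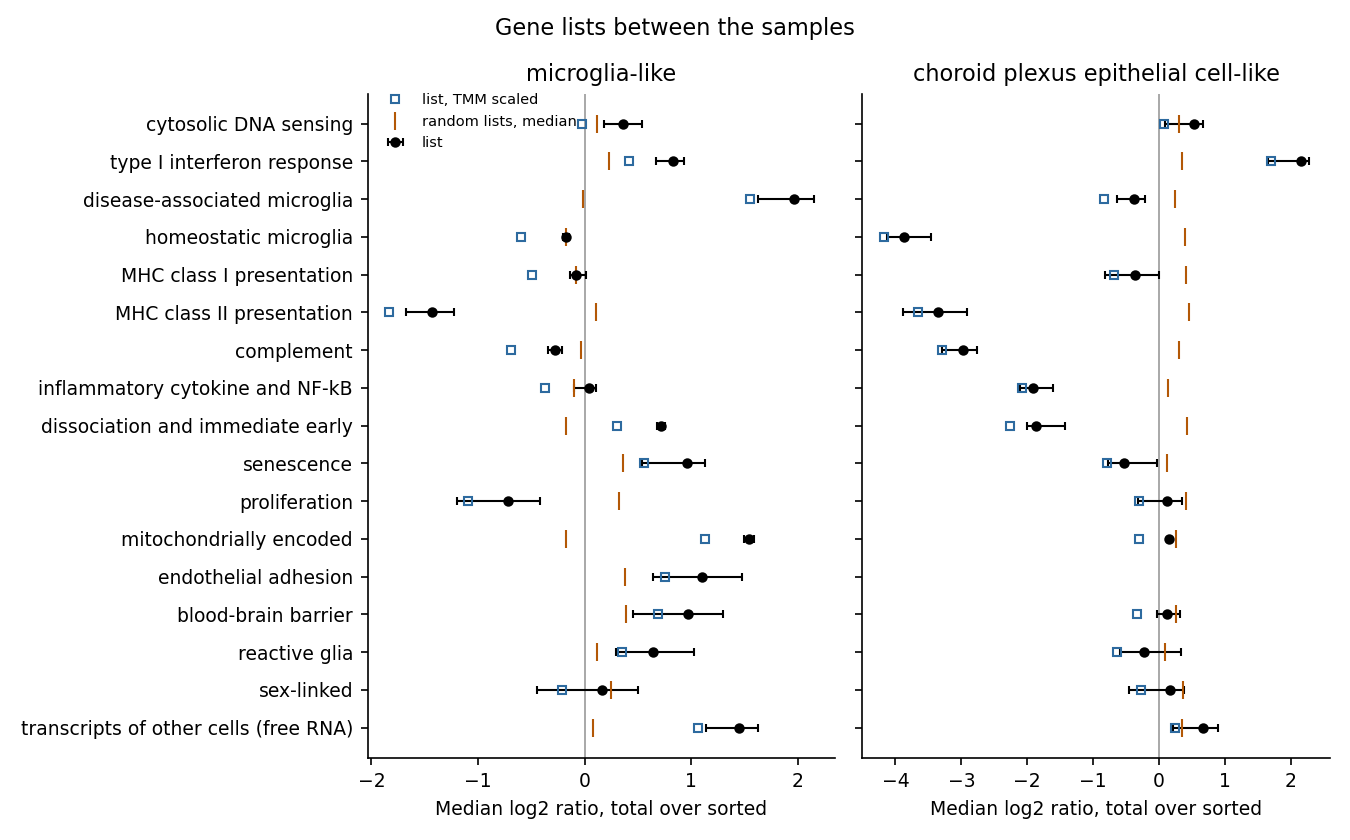
Median log2 ratio (total over sorted, horizontal axes) of each gene list in microglia-like and choroid plexus-like cells: circles with 95% intervals (counting error only) from CPM, open squares after TMM scaling, and vertical ticks the median of random lists. The interferon list lay at 0.83 and 2.15, and the DNA sensing list of microglia-like cells at 0.36 moved to −0.02 with TMM.

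Single genes of microglia-like cells with the largest ratios, whose ranges over suffixes do not overlap between the samples, included the transcription factor genes Jund, Cebpb, Cebpa and Klf2 on the side of the total sample. Xist, the RNA that silences an X chromosome in female cells, had 0 UMIs in sorted and 1143 CPM in total microglia-like cells, at least 3458-fold higher; the sorted sample is labelled male and the total sample male and female. Jund, an AP-1 transcription factor gene, was at 113 and 3282 CPM in the sorted and total samples, 29.1-fold [27.2–31.0]. Cebpb (17.3 and 432 CPM), Cebpa (36.8 and 440.4 CPM) and Klf2 (55.9 and 679 CPM), transcription factor genes of myeloid cells, were 24.95-fold, 12.0-fold and 12.2-fold higher. The heat shock gene Hspa1b was at 163 and 2064 CPM, 12.7-fold higher, but its near-identical neighbour Hspa1a was at 1844 and 1815 CPM, so the division of reads between them is uncertain. AY036118, a noncoding RNA gene on chromosome 17 at 39847113 to 39848035 in a region of ribosomal RNA repeats, was 45.0-fold higher, Lars2 36.5-fold, Taf10 21.7-fold, Ube2m 14.9-fold and Otulin 10.8-fold. Nrgn, a neuronal gene, was 17.1-fold higher. On the side of the sorted sample, the immunoglobulin gene Igkc was 28.3-fold [13.6–70.6] higher at 68.1 against 2.41 CPM, and the choroid plexus gene Enpp2 3.75-fold. The stress-response genes Klf10 (6.15-fold), Oser1 (4.46-fold) and Gadd45g (3.86-fold) and the class II gene H2-Ab1 (3.29-fold) were also higher there, as were Gstp1 (5.82-fold), Lrch4 (4.53-fold), Clu (3.59-fold), Grcc10 (3.19-fold) and Chst12 (3.098-fold). Rpl13a-ps1 (4.19-fold) is a pseudogene that can take reads of its parent gene. Leaving out a suffix moved some of these levels by over 1.5 times. In the sorted sample, Oser1 was at 85.3 CPM and Taf10 at 2.29 CPM without suffix 2, Igkc at 41.7 CPM without suffix 3 and AY036118 at 7.76 CPM without suffix 1. On the side of the total sample, Enpp2 was at 27.5 CPM and Rpl13a-ps1 at 8.88 CPM without suffix 1, and Igkc at 0.827 CPM without suffix 2.

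Markers of other classes differed as well. Ttr, the main transcript of choroid plexus, was at 8592 CPM in microglia-like cells of the sorted and 533 CPM in those of the total sample, and Hba-a1 at 1206 and 127 CPM. S100a8, a neutrophil gene, was at 75.8 and 0.344 CPM, the latter from 1 UMI, a ratio of 220.2 [39.4–8712]; that UMI was in suffix 2. In the total sample, Ttr was at 343 CPM without suffix 1 and Hba-a1 at 26.1 CPM without suffix 3, and Meg3 in the sorted sample was at 4.57 CPM without suffix 2. The neuronal genes Meg3 (6.94 and 336 CPM) and Snap25 (3.31 and 86.4 CPM) were higher in the total sample. The list of transcripts of other cells had a median of 1.45, but its summed level was 12251 CPM in the sorted and 1307 CPM in the total sample.

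In choroid plexus-like cells, interferon response genes were higher in the total sample. Genes of microglia and other immune cells were higher in the sorted sample, where such cells were more abundant. The interferon list had a median log2 ratio of 2.15 [1.65–2.27], against 0.35 for random lists and 1.70 with TMM, above all random lists, with 18 of 19 members higher in the total sample (16 with TMM). Isg15, a ubiquitin-like interferon product, was at 1.13 and 58.3 CPM in the sorted and total samples, 51.4-fold [30.4–93.7]. Ifit1 (0.453 and 37.9 CPM), Ifi27l2a (23.95 and 201 CPM), Ifitm3 (52.7 and 239 CPM) and Bst2 (142 and 385 CPM) were higher too, while Slfn2 was lower (2.27 and 0.303 CPM, 1 UMI). Without suffix 1 of the total sample the median was 1.48, with Isg15 at 24.8 CPM, Ifit1 at 12.2 CPM and Ifi27l2a at 126 CPM, and Slfn2 at 0 CPM. Ifit1 in the sorted sample was at 0.277 CPM without suffix 4. In suffixes 3 and 4 of the total sample, Isg15 (1.36 and 0 CPM) and Ifitm3 (62.4 and 37.9 CPM) were within or below the range of the suffixes of the sorted sample. TMM lowers the log2 ratios of this class by up to 0.46, and the median of all genes with 50 CPM was 0.35.

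Several other lists of choroid plexus-like cells were lower in the total sample, among them lists of immune genes and immediate early genes. Complement genes had a median of −2.98, with C1qb at 175 and 8.19 CPM and C1qc at 155 and 4.86 CPM, the class II list −3.35, the homeostatic microglia list −3.87, the cytokine list −1.91 and the disease-associated list −0.37. The named genes higher in the sorted sample were all immune genes, with Ccl4 at 61.3 CPM against 0.607 CPM from 2 UMIs (101-fold [27.9–835]), Ctss at 37.8-fold, Selplg at 46.4-fold, Cd74 at 34.0-fold, Csf1r at 28.8-fold and Tyrobp at 24.9-fold. Cd74 in the total sample was at 0.438 CPM without suffix 2, C1qc at 3.13 CPM and Ccl4 at 0.391 CPM without suffix 3, and Selplg at 0 CPM without suffix 4. Immediate early genes had a median of −1.86, opposite to microglia-like cells, with Fos at 63.4 and 5.16 CPM but Jund at 14.7 and 308 CPM. Class I genes had a median of −0.37, the senescence list −0.53 (0.031 without suffix 1 of the sorted sample) and the reactive glia list −0.22. The DNA sensing list (0.52) lay at percentile 79.2 and moved to 0.07 with TMM. Mitochondrially encoded (0.15), blood-brain barrier (0.12), proliferation (0.12) and sex-linked (0.16) lists lay between percentiles 22.4 and 28.1 of random lists, and their directions flipped with TMM, to −0.31, −0.33, −0.31 and −0.28. The list of transcripts of other cells had a median of 0.66. Named genes higher in the total sample were AY036118 (211-fold), Lars2 (67.6-fold), Taf10 (41.6-fold), Jund (21.01-fold), Sap30l (18.9-fold), Hopx (17.0-fold), Hras (16.5-fold) and Ube2m (12.9-fold). AY036118 was at 287 CPM in the total sample without suffix 2 and at 1.14 CPM in the sorted sample without suffix 1. Of these 8, AY036118, Jund, Lars2, Taf10 and Ube2m were also among the 12 named in microglia-like cells.

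Oligodendrocyte-like cells, with 151 sorted and 119 total cells, differed most in lists of immune and microglial genes. The complement list (−5.64), the class II list (−5.62), the cytokine list (−4.30), the homeostatic microglia list (−4.10) and the class I list (−1.53) were lower in the total sample, as was the disease-associated list (−0.86). Mitochondrially encoded genes had a median log2 ratio of 0.63 [0.57–0.71], against −0.27 for random lists. The DNA sensing (0.19), interferon (0.24), immediate early (0.13) and reactive glia (0.18) lists lay near random lists, between percentiles 38.4 and 67.5, and the immediate early list was at −0.063 without suffix 2 of the sorted sample. The blood-brain barrier list had a median of 1.35, the sex-linked list −0.60 and the list of transcripts of other cells −0.39. Among reactive glia genes, C4b was at 48.9 and 143 CPM and Serpina3n at 6.67 and 42.2 CPM in the sorted and total samples, while the protease gene Klk6 was lower in the total sample (1020.2 and 419.6 CPM). Without suffix 1 of the total sample C4b was at 78.3 CPM and Serpina3n at 13.2 CPM, and without suffix 3 at 227 and 65.5 CPM. In the sorted sample C4b was at 27.5 CPM without suffix 3 and Serpina3n at 2.87 CPM without suffix 4. Il33, an alarmin gene of oligodendrocytes, was at 742 and 740.2 CPM. TMM lowers the log2 ratios of this class by up to 0.08.

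Subclusters of the microglia-like cells fell mostly by sample, apart from a small interferon-led group found in both. Subcluster 3, led by Ifit3, Ifitm3 and Isg15, held 1.83% [1.44–2.28] of sorted and 1.07% [0.347–2.47] of total microglia-like cells, the latter 5 cells. These shares cannot be compared between the samples. Subcluster 2 took 97.7% of the total cells and 0 sorted cells, so total cells with high interferon genes may lie in it. Its share was 1.83%, 0.676%, 3.62% and 2.47% in suffixes 1 to 4 of the sorted sample, and 0%, 5.13%, 0.671% and 0% in those of the total sample. Subcluster 4, led by Lpl, Lgals3 and Plaur, held 0.937% of sorted cells and 0.213% of total cells, the latter 1 cell. Subclusters 0 (led by Dynlt1c and Usp50) and 1 (led by haemoglobin genes and Nfkbia) held 52.6% and 44.6% of the sorted cells, and subcluster 2 (led by Xist and Jund) held 97.7% of the total cells, so these 3 may be the library and not a state. No subcluster had 3 or more cytokine genes among its 10 leading genes at the resolution used, whereas at resolution 1 such subclusters held 26.4% of the sorted microglia-like cells.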

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

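The tests of Tmem173 against genes of like level and the test of mitochondrial yield were chosen after the results were seen.

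Barcode suffixes, which the labels put in no group, drew attention because Tmem173 levels in microglia-like cells lay far apart between them. The highest suffix was 158 times the lowest in the sorted sample and 99.6 times in the total sample. A lower depth or capture of microglial RNA in some suffixes was argued against: the log2 ratio of highest to lowest suffix, 6.74 in the sorted sample, was at percentile 100 of 1470 genes of like level, whose median was 0.32. In the total sample it was 6.24, at percentile 99.9 of 1894 genes with a median of 0.56, and 2 genes lay above it. Suffixes that differ in genotype may be a candidate source, since knockout and wild type mice were pooled, but no source used here maps suffixes to mice and this was not tested.

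Microglia-like cells differed between the samples in many genes. A difference in chemistry or handling that acts on all cells of a sample is open. Log2 ratios in microglia-like and choroid plexus-like cells had a Pearson correlation of 0.783 across 1559 genes, as this explanation predicted. Age, sex or the sort could give such a correlation too, so it does not tell them apart. For sex, Xist over the suffixes of the total sample was at 2.40 to 7.02 CPM in choroid plexus-like and 908 to 1283 CPM in microglia-like cells. Ddx3y, on the Y chromosome, was at 36.6 to 63.5 CPM in those choroid plexus-like cells, near the sorted sample (35.6 to 47.7 CPM). Few of them may thus be female, which makes sex a weaker candidate for ratios shared by both classes. The immediate early list went opposite ways in these classes, at 0.72 and −1.86. The barcode pools given below, 797 against 3362, differ as they would with 2 chemistries, although the labels name the same chemistry for both samples. The sequences shared between the samples, also given below, argue against 1 barcode list for both. Whether this caused the gene differences was not tested. Free RNA of other cells is open for the sorted sample, where 58.3% of the 12 named genes were at least as high in another class. In the total sample 41.7% of 12 were, short of the majority predicted beforehand. So few genes, with markers of other classes left out, cannot decide it, and it stays open there too. The list of transcripts of other cells had a median of 1.45 in microglia-like cells, at percentile 99.9, with 5 of 8 members higher in the total sample. Its summed level went the other way, at 12251 CPM in the sorted and 1307 CPM in the total sample, with Ttr at 8592 and 533 CPM. The median thus does not measure the amount of such transcripts. Age, sex and the sort differ together with the library and stay open as untested.

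Neuron-like barcodes of the total sample had few mitochondrial UMIs (1.84%). Nuclei are a candidate source: ribosomal protein genes had 1.31% of their UMIs against 6.35% in endothelial-like cells, a ratio of 0.206, and Malat1, a nuclear RNA, had 5.06% against 3.06%. Astrocyte-like cells of the same sample had 1.19% and 9.49%, with 3.04% mitochondrial UMIs. The low ribosomal share was thus not particular to neuron-like barcodes. A low mitochondrial yield of the whole sample is argued against by endothelial-like cells, which had 7.16%. Microglia-like (3.49%) and astrocyte-like cells (3.04%) lay nearer to neuron-like cells, so this answer depends on the class used. No biological explanation was tested, because the design gives none.

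Other values drew attention because they come from barcodes or barcode sequences outside the comparisons. Haemoglobin genes held 54.3% of the UMIs of barcodes removed by the filter in the sorted sample and 30.8% in the total sample, against 0.665% and 1.57% in kept cells. The number of barcode sequences shared between suffixes gives a pool, in units of 1000 sequences, of 797 [645–998] in the sorted sample, from 85 shared sequences, and 3362 [2241–5304] in the total sample, from 23. Ifitm3 in choroid plexus-like cells of the total sample was 10.3 times as high in its highest as in its lowest suffix.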

How the results depend on the processing

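The settings without Ttr, without the cytokine-led cluster and with the unnamed Spp1-led cluster added were chosen after seeing the data, as was the summary of interferon-led subclusters. No paired analysis was possible because the groups share replicate number 1 only and no result comes from a test. Of the settings tried, 90 left a main result within its counting interval, 75 moved it and 2 reversed it, and for other results 660, 199 and 13 did; the cause was not tested. A direction counts as reversed only where the interval of the value left out 0; other TMM flips stand in the results above. Directions reversed as follows. With TMM, DNA sensing in microglia-like cells went to −0.023 and mitochondrial genes in choroid plexus-like cells to −0.31. Without the cytokine-led cluster the disease-associated list went to −0.14, and without total suffix 1 the senescence list to −0.17. In choroid plexus-like cells, DNA sensing went to −0.0013 (stricter filter) and −0.17 (no UMI minimum), senescence to 0.092 (doublets removed), 0.064 (50 UMIs) and 0.031 (without sorted suffix 1), mitochondrial genes to −0.16 (stricter) and −0.14 (without Ttr), and transcripts of other cells to −0.018 (50 UMIs). In oligodendrocyte-like cells, immediate early genes went to −0.063 (without sorted suffix 2) and reactive glia to −0.042 (looser filter) and −0.43 (no minimum).

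Shares moved as follows. Microglia-like in the sorted sample: looser 44.5%, stricter 49.1%, resolution 0.5 44.1%, resolution 2 38.3%; in the total sample: looser 5.97%, stricter 7.73%, resolution 0.5 6.085%, clustered alone 2.15%, equal weight 5.82%. Choroid plexus-like was 22.9% (looser), 26.1% (stricter) and 18.6% (alone) in the sorted sample, and 3.73% (stricter) and 4.15% (equal weight) in the total sample. Neuron-like was 56.7% (looser), 62.3% (stricter), 47.9% (alone) and 56.2% (equal weight). The microglia-like interferon list was 1.13 (stricter), 0.53 (pseudocount 10), 0.42 (TMM) and 0.33 (without the cytokine-led cluster), the disease-associated list 1.21 (pseudocount 10) and 1.55 (TMM), and the homeostatic list −0.24 (looser), −0.14 (stricter), −0.22 (equal weight), −0.59 (TMM) and −0.092 (without that cluster). The choroid plexus-like interferon list was 2.60 (stricter), 1.16 (pseudocount 10), 1.54 (no minimum) and 2.60 (50 UMIs). Tmem173 in sorted microglia-like cells was 146 CPM (equal weight), 179 (without mitochondrial and ribosomal genes) and 184 (TMM), and in total ones 155 and 118 (the last 2 settings). Leaving out each suffix gave ranges of 36.8% to 45.9% (microglia-like, sorted), 4.41% to 5.59% (total), 24.6% to 25.4% and 2.27% to 4.00% (choroid plexus-like), 56.8% to 59.4% (neuron-like), 0.28 to 0.45 (DNA sensing, microglia-like), 0.014 to 1.08 (interferon), 0.54 to 2.41 (disease-associated), −0.27 to −0.10 (homeostatic), −0.17 to 1.30 (senescence), −0.53 to 0.031 (senescence, choroid plexus-like), −0.063 to 0.64 (immediate early, oligodendrocyte-like), 1.48 to 2.45 (interferon, choroid plexus-like), and 46.7 to 253 CPM (Tmem173, sorted) and 58.6 to 190.6 CPM (total).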

Other observations

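Choroid plexus-like cells of the total sample held interferon genes at levels that lay apart between suffixes. In suffixes 1 to 4, Ifitm3 was at 389, 385, 62.4 and 37.9 CPM, Isg15 at 157, 59.3, 1.36 and 0 CPM, Ifi27l2a at 422, 261, 42.1 and 22.5 CPM, and Bst2 at 609, 557, 134 and 139 CPM. Those of the sorted sample had Ifitm3 at 54.6, 36.8, 49.3 and 75.2 CPM.

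Microglia-like cells also had genes that lay apart between suffixes 1 to 4. Apoe was at 11753, 15649, 738 and 543 CPM in the total sample and at 1047, 907.5, 1000.1 and 2483 CPM in the sorted sample. Spp1 was at 2433, 676, 9.91 and 5.83 CPM in the total and 3.82, 16.8, 5.56 and 126 CPM in the sorted sample. Ifit3 was at 1.54, 154, 19.8 and 3.50 CPM in the total sample. Ccl4 was at 2418, 2965, 957 and 643 CPM in the total sample.

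Class shares differed between suffixes 1 to 4 as well. Microglia-like cells were 48.5%, 56.0%, 29.8% and 27.5% of the sorted sample, T cell-like cells 3.61%, 2.82%, 9.69% and 9.18%, and border macrophage-like cells 2.69%, 3.07%, 5.11% and 6.90%. In the total sample, choroid plexus-like cells were 5.49%, 7.61%, 1.70% and 1.80%, microglia-like cells 9.52%, 5.30%, 4.09% and 4.37%, and neuron-like cells 49.1%, 54.8%, 59.9% and 61.1%.

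Xist had 6 UMIs in all kept cells of the sorted sample and 34867 in those of the total sample. In suffixes 1 to 4 of the total sample, it was at 1037, 908, 1214 and 1283 CPM in microglia-like cells and at 2.40, 4.94, 6.78 and 7.02 CPM in choroid plexus-like cells.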
